A study of Mus musculus with 6 samples.

How the data were processed

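RNA of mouse oocytes at the germinal vesicle stage, before meiosis resumes, was measured by sequencing in 6 samples of 50 oocytes each. In 3 samples the oocytes had grown in vitro, inside follicles taken from 10 to 12 day old F1 females and cultured on membrane inserts in a medium with serum, insulin, transferrin, selenium and follicle stimulating hormone. In the other 3 samples the oocytes had grown in vivo and were released from the ovaries of F1 females 7 to 11 weeks old. Per the labels, cDNA was made and amplified from 10 ng of total RNA with a low input kit, and the submitters named BWA, with no version, and the genome build mm9.

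The values came from the authors' deposited table of 10896 genes. In it the authors gave a signal per gene and group, the mean number of normalised reads over the samples of a group, with scale factors that were not stated. The authors also gave a log2 ratio of in vivo over in vitro, a gene length, and a PPEE. It was read here as the posterior probability that a gene is equally expressed in both groups, from the usual meaning of the term, since no source at hand named the tool that made it. Every call rests on this reading, and a PPEE is not a p-value. Recomputing the deposited log2 ratio from both means required adding 0.599 to each mean, and the largest difference left was 4.11e-09. The means were not scaled by gene length, since their Spearman correlation with length across genes was 0.061 in vitro and 0.0954 in vivo. They summed to 6.86e+06 in vitro and 6.62e+06 in vivo. Spreadsheet software had turned 16 gene symbols into dates, and these were restored from the gene identifiers. Of all identifiers, 10875 were found in the RefSeq annotation of build GRCm38, which was used for names. Base composition and sequence searches used GENCODE transcript sequences, matched by gene symbol. No coordinates are given, because build GRCm38 differs from the build the submitters named.

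The tests planned before the data were examined needed values per sample, which the columns of group means do not carry, so they could not be run as planned. In their place a gene was called when the PPEE in the authors' deposited table was below 0.05. Folds were taken from the 2 group means, and no SD or n of the samples belongs to them. For the 30 gene lists fixed before the data were examined, the called members in each direction were counted against all other genes of the table by Fisher's exact test, 1-sided. The 54 tests of the 27 lists with at least 5 measured members were adjusted together by the Benjamini-Hochberg method. Each list's median change was also set beside 10000 random lists matched on mean, and on mean and gene length. As an alternative added after seeing the data, the calls of each list and term were counted against genes matched in the same way, by an exact test over strata. The Gene Ontology terms of the deposited table were tested in the same way, each against the genes with a term of its kind, for terms of 10 to 500 genes. There were 1972 such tests of 986 terms.

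Reads per library were recovered for part of the genes, a step added after seeing the data. A mean of 3 libraries is a sum of whole reads, each multiplied by 1 step per library. These steps were found from repeated values among low means, and every mean up to 200 was then solved for whole reads, to the 10 significant digits of the table. A single whole solution was found for 95.1% of such means in vitro and 95.4% in vivo. Shifted values that should have none gave a solution in 4.16% of cases in vitro, or 16.1% between means of 100 and 200, and in 0.0154% in vivo. Tested on 10 simulated groups, the steps were found in 9, where at least 99.98% of genes with whole reads were solved once and at least 99.89% of the solutions were right. In the simulated group with wrong steps 73.1% were solved and 0.227% of these were right. Among genes with means up to 50 in the real data, the sums of normalised recovered reads of the libraries lay between 0.960 and 1.06 times their group's average, which the solving did not impose. Both groups were solved for 5803 genes. The libraries were named A, B and C by their step size, since nothing ties them to the replicate numbers of the labels. Their size factors were 1.09, 0.965 and 0.806 in vitro and 1.24, 1.13 and 0.885 in vivo. The recovered reads were analysed with limma voom, with library sizes in proportion to the size factors, 2-sided tests and a Benjamini-Hochberg adjusted p below 0.05. With 200 changed genes planted among 5803 simulated ones, limma voom found 10.0% of the 2-fold and 85.0% of the 4-fold changes, and 1.04% of its calls were unchanged genes. Gene lists with at least 5 recovered members were tested with camera, at a preset correlation of 0.01 and with an estimated one, and with fry. Correlations between libraries were compared within and between groups with an exact permutation test over the 10 splits of the 6 libraries.

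Genes to name were chosen by a rule written before the data were examined. The rule took, among called genes, the 8 with the largest change in each direction whose 3 values in 1 group all lay above the 3 of the other and whose higher mean was at least 10, leaving out unnamed gene models. This part could be applied only to the 547 called genes with recovered reads. The rule also took up to 4 members with the lowest PPEE from each list past its test or with at least 3 calls, up to 2 from each other list, and 12 fixed oocyte genes. Alternatives covered the threshold, the scaling, the offset, a filter on low means, the list background and members, the test, and leaving out each library. A count of detected genes per library, which was planned, was left out because the table lists only genes above a level, with 6.74 as the lowest value of the larger mean. Intervals on shares of genes are Wilson 95% intervals and cover counting error only. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, R 4.3.3 with limma 3.58.1, and BLAST 2.17.0.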

Results

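The series compared the transcriptomes of mouse oocytes at the germinal vesicle stage that had grown in cultured follicles with those of oocytes that had grown in the ovary, with 3 samples of 50 oocytes in each group. Every in vitro sample came from females 10 to 12 days old and every in vivo sample from females 7 to 11 weeks old. A difference due to culture can therefore not be told apart from one due to donor age in any comparison below. The data were group means of normalised reads for 10896 genes, and the depth of each sample was not stated. Reads per library could be recovered for 5803 genes with means up to 200, where the libraries held between 288437 and 431329 reads. These reads carried no molecular identifiers, so intervals cover counting error only. Nothing in the labels says whether the 3 samples of a group came from separate cultures or animals. The p-values of limma and fry on recovered reads therefore measure the spread between samples only. Camera's p-values compare the genes of a list with all other genes, and at the preset setting they assume a correlation between genes of 0.01. Those of Fisher's exact test and of the tests against matched genes count called genes. They take genes as independent and hold no spread between samples beyond what the PPEE holds. Group means taken from the authors' deposited table have no SD here, while values from recovered reads are given with their SD over 3 libraries.

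Most genes differed little between oocytes grown in vitro and in vivo, and called genes included Bmp15, Nlrp5, Cenpf and Dnmt1. By the authors' deposited table, 1640 of 10896 genes (15.1%) were called, 735 higher and 905 lower in vitro, and the median size of a called change was 1.66-fold. Among these, 480 changed at least 2-fold, 251 upward and 229 downward in vitro. A further 661 genes differed at least 2-fold in the authors' deposited table without being called. Of all genes, 89.5% differed less than 2-fold (95% Wilson interval 88.9 to 90.1), and the SD of the log2 change across genes was 0.63. The Spearman correlation of both group means across genes was 0.968. Genes are not independent replicates, and this value comes from means over samples.

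**Figure D1:**
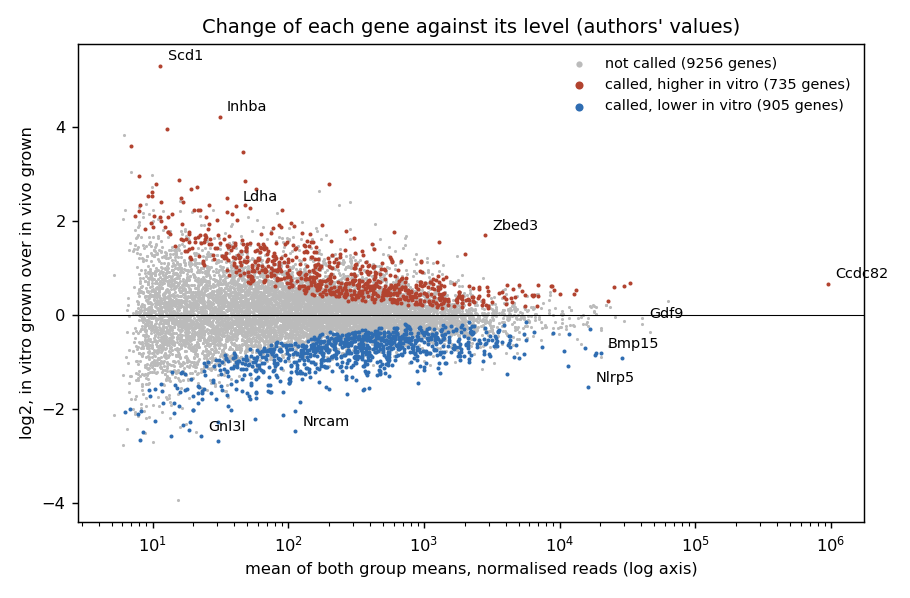
Change of each gene (log2 of in vitro over in vivo, from the authors' deposited table) against the mean of both group means in normalised reads, on a log axis. Each point is a gene: 735 called higher in vitro (red), 905 called lower (blue) and all others (grey). The point of Scd1, listed at 0 in vivo, has its height set by the offset of 0.599 added to both means.

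Among the largest called increases in vitro were Scd1, Inhba and Hsd3b1. Scd1 (gene identifier 20249), a desaturase that makes monounsaturated fatty acids, had a mean of 22.9 normalised reads in vitro and was listed at 0 in vivo in the authors' deposited table, with a PPEE of 0.00589. Its recovered reads were 44, 8 and 16 in the in vitro libraries and 0 in each in vivo library. Inhba (gene identifier 16323), a subunit of activins and of inhibin, was 22.4-fold higher in vitro in the authors' deposited table, with a listed PPEE of 0. In recovered reads Inhba stood at 60.1 ± 5.27 normalised reads in vitro (SD, n = 3 libraries) against 2.69 ± 2.38 in vivo (SD, n = 3 libraries). Nap1l5 was 11.8-fold higher, Kif1a, a kinesin, 10.6-fold, Tbc1d13 8.45-fold, Hsd3b1, a steroid dehydrogenase, 8.38-fold and Taf6l 7.48-fold in the authors' deposited table. These folds rest on few in vivo reads. In recovered reads, leaving out in vivo library C raised the fold of Taf6l to 34.7, of Inhba to 33.9 and of Nap1l5 to 28.8, and left Tbc1d13 with 0 in vivo reads. Leaving out in vivo library A raised that of Kif1a to 33.0 and of Hsd3b1 to 15.8. Other omissions lowered folds: that of Tbc1d13 was 5.33 without in vitro library B. Taf6l stood at 5.12-fold without in vivo library B, and Inhba at 14.9-fold without in vivo library A. AI848285 had 7, 17 and 13 recovered reads in vitro and 1, 1 and 0 in vivo.

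Among the largest called decreases in vitro were Nrcam, Gadl1 and Adam8. Nrcam (gene identifier 319504), a cell adhesion molecule, was 5.64-fold lower in vitro in the authors' deposited table, with a listed PPEE of 0. Its recovered level was 33.9 ± 12.8 normalised reads in vitro against 191 ± 34.7 in vivo (SD, n = 3 libraries each). Gadl1 was 8.19-fold lower, Grb7, an adaptor of receptor signalling, 6.85-fold, Ttll7 6.77-fold and Gnl3l, a nucleolar protein, 6.47-fold lower in the authors' deposited table. Limma voom on recovered reads did not call Gadl1 (adjusted p = 0.0662) or Ttll7 (adjusted p = 0.0680). In recovered reads, Ttll7 was 20.9-fold lower without in vitro library A, Grb7 10.7-fold without in vitro library C, Sh2d4b 9.23-fold without in vitro library A and Gadl1 5.33-fold without in vivo library A. Sh2d4b was 5.90-fold lower, Krt71 5.51-fold and Adam8, a membrane metalloproteinase, 5.06-fold lower in the authors' deposited table. Adam8 stood at 10.00 ± 2.15 normalised reads in vitro and 50.6 ± 12.9 in vivo (SD, n = 3 libraries each). Among called genes without recovered reads, chosen after their values were seen, Lurap1l was 6.94-fold higher in vitro, and Plek and Enpp2 were 3.23-fold and 3.03-fold lower in the authors' deposited table.

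**Figure D2:**
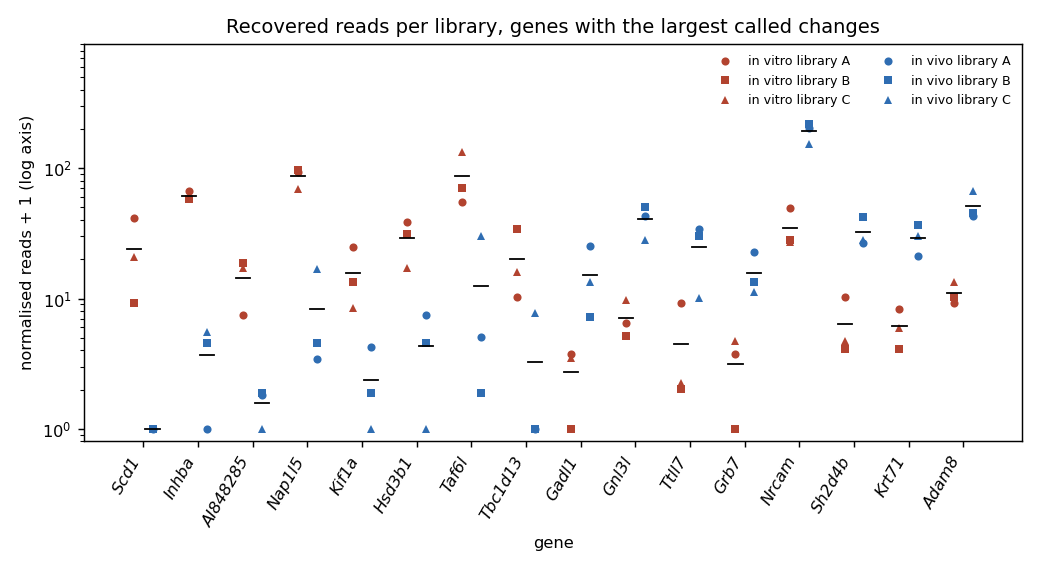
Recovered normalised reads plus 1, on a log axis, in each of the 3 in vitro (red) and 3 in vivo (blue) libraries for the 8 largest called increases and the 8 largest called decreases, with bars at the group means. For every gene the libraries of the groups do not overlap, which the choice of these genes required.

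Genes that oocytes need for the egg coat and for signals to their follicle mostly were not called. Of 10 measured zona pellucida and secreted factor genes, 0 were called higher and 1 lower in vitro (adjusted p = 1 for either direction), and the median log2 change of the list was -0.20. That gene was Bmp15, a growth factor secreted by oocytes, at 1.76-fold lower in vitro in the authors' deposited table, with a PPEE of 1.52e-08. Gdf9, its partner, was 1.14-fold lower with a PPEE of 0.979 in the authors' deposited table. The zona genes Zp1, Zp2 and Zp3 were 1.53-fold, 1.16-fold and 1.59-fold lower in the authors' deposited table, with PPEE of 0.344, 0.930 and 0.913. Kit, the receptor through which follicle cells act on oocyte growth, was called, at 1.84-fold lower with a PPEE of 0.00101 in the authors' deposited table. Mos, the kinase behind the arrest of mature eggs, was 1.45-fold higher in vitro in the authors' deposited table, with a PPEE of 0.313. The maternal genes Npm2, Dppa3 and H1foo were 1.09-fold, 1.11-fold and 1.15-fold higher, with PPEE of 0.897, 0.997 and 0.984 in the authors' deposited table. Of the 12 oocyte genes fixed before the data were examined, 4 were called, all lower in vitro: Bmp15, Kit, Nlrp5 and Dnmt3l.

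The subcortical maternal complex, a protein assembly that the early embryo inherits from the egg, held large changes in both directions. Of its 8 measured genes, 2 were called higher and 3 lower in vitro (adjusted p = 0.403 and 0.140), and the median log2 change was -0.57. Nlrp5 was 2.89-fold lower in vitro, Tle6 2.11-fold and Nlrp2 1.99-fold lower in the authors' deposited table, with PPEE of 5.19e-09, 3.27e-11 and 6.13e-09. Zbed3 was 3.23-fold higher in the authors' deposited table, with a PPEE of 8.97e-05. Khdc3, the other called increase, which the rule for named genes did not take, was 5.76-fold higher from 4.95 to 28.5 mean normalised reads in the authors' deposited table.

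Genes of the spindle and kinetochore, which part chromosomes in meiosis, were called lower in vitro more often than all other genes of the table, a result that most alternatives did not keep. Of 32 measured members, 9 were called lower and 4 higher, and the count of lower calls passed its test (adjusted p = 0.0476, Fisher's exact test). Cenpf, a kinetochore protein, was 1.92-fold lower in vitro, Bub1b, a checkpoint kinase, 1.79-fold, Prc1, a midzone protein, 1.44-fold and Ndc80 1.37-fold lower in the authors' deposited table. Their PPEE in the authors' deposited table were 0 as listed, 5.15e-08, 2.57e-11 and 3.38e-11. Named after their values were seen, the 4 called higher were Sgol2, a cohesin protector, at 2.08-fold, Mad2l1, a checkpoint protein, at 1.24-fold, Sgol1 at 1.19-fold and Cdca8 at a log2 change of 0.14 in the authors' deposited table. The list no longer passed against genes matched on mean (adjusted p = 0.181) or on mean and length (adjusted p = 0.118), tests added after seeing the data. Nor did it pass at a PPEE below 0.01 (adjusted p = 0.107), with at least a 1.5-fold change (adjusted p = 0.516), with a mean of at least 10 over both groups (adjusted p = 0.0576) or without genes at a PPEE of exactly 1 (adjusted p = 0.0646). It passed without shared members and after centring, neither of which altered its counts. Its median change lay at percentile 5.30 of random lists matched on mean and at percentile 2.05 of those matched on mean and length. Over its alternatives the adjusted p ranged from 0.0476 to 0.516, and too few of its members had recovered reads for a test per library.

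Other meiotic lists held few calls. Of 20 genes of meiotic arrest and resumption, 1 was called higher and 0 lower in vitro (adjusted p = 1 for either). Fzr1, an activator of the anaphase promoting complex, was 2.18-fold higher with a PPEE of 0.0302 in the authors' deposited table, while Gpr3, the receptor that keeps oocytes arrested, was 1.69-fold lower with a PPEE of 0.0501. Of 16 genes of meiotic cohesion and recombination, 1 was called higher and 1 lower (adjusted p = 1 for either). Sycp3, an axis protein of meiotic chromosomes, was 2.47-fold higher with a listed PPEE of 0, and Stag3, a meiotic cohesin, 3.58-fold lower with a PPEE of 0.00674 in the authors' deposited table. Stag3 differed between in vitro libraries, with 31 recovered reads in library A, 6 in library B and 3 in library C. Without in vitro library A it was 9.23-fold lower in recovered reads. In the 9 recovered genes of this list, limma's fry test, which does not compare a list with other genes, gave an adjusted p of 0.00608 for lower values in vitro. Camera, which does compare with other genes, gave an adjusted p of 0.163 at the preset correlation and an adjusted p of 0.808 with an estimated one. The median log2 change of these genes was -0.24, -0.24 and -0.22 in in vitro libraries A, B and C, and in vivo library A stood at -0.23 against the other in vivo libraries.

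The list of DNA methylation and imprint setting held 19 measured genes, of which 6 were called lower and 2 higher in vitro (adjusted p = 0.0609 and 1). The lower calls passed at a PPEE below 0.01 (adjusted p = 0.0338), and over the alternatives the adjusted p ranged from 0.0338 to 0.483. Kdm1b, a histone demethylase needed for maternal imprints, was 2.38-fold lower, Dnmt1, the maintenance methyltransferase, 1.64-fold, Uhrf1, its recruiter, 1.60-fold and Dnmt3a, the oocyte's de novo methyltransferase, 1.49-fold lower in the authors' deposited table. Their PPEE were 3.15e-05, 0.000361, 2.30e-09 and 0.000397 in the authors' deposited table. Dnmt3l, the cofactor of Dnmt3a, was 1.33-fold lower with a PPEE of 0.00107 in the authors' deposited table. Named after their values were seen, Dnmt3b was 1.42-fold lower, and Zfp57 and Kdm1a were 1.29-fold and 2.11-fold higher in the authors' deposited table. The median of the whole list lay at +0.15 on the log2 scale, opposite to the larger count of calls. Among the 5 members with recovered reads, limma voom called 0 over all genes and 2 higher adjusted over the list alone. Of 15 imprinted genes, 1 was called higher and 1 lower (adjusted p = 1 for either): Usp29 was 1.32-fold higher and Mest 1.55-fold lower in the authors' deposited table.

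Genes of small RNA pathways that silence transposons were called mostly lower in vitro, without passing Fisher's test. Of 19 piRNA and RNA interference genes, 4 were called lower and 1 higher (adjusted p = 0.330 and 1). Piwil2 was 2.84-fold lower, Tdrd9 2.45-fold, Ago2 1.79-fold and Tdrd1 1.71-fold lower in the authors' deposited table, and Ago3, named after its value was seen, was 1.34-fold higher. Piwil2 stood at 19.6 ± 3.42 normalised reads in vitro and 55.7 ± 13.1 in vivo (SD, n = 3 libraries each). Of 7 members with recovered reads, limma voom called 1 lower over all genes and 3 lower adjusted over the list alone. Their median log2 changes against the in vivo mean were -0.27, -1.26 and -1.08 in in vitro libraries A, B and C. Camera gave these members an adjusted p of 0.0664 for lower values at the preset correlation, 0.808 with an estimated one, 0.0288 without in vitro library A and 0.392 without in vitro library B, and fry gave an adjusted p of 0.224. Of 15 oocyte transcription and chromatin factors, 1 was called higher and 1 lower (adjusted p = 1 for either). These were Obox5 at 1.54-fold higher and Gtf2a1l, a germ cell form of a general transcription factor, at 1.53-fold lower in the authors' deposited table. Of 18 genes of maternal mRNA storage and decay, 1 was called higher and 0 lower (adjusted p = 1 for either), and the median log2 change was 0.29. It was Dcp2, a decapping enzyme, at 1.42-fold, while Pan3, a deadenylase subunit, was 2.09-fold higher with a PPEE of 0.0882 in the authors' deposited table.

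Genes of glucose and sterol metabolism were called in both directions. Of 17 glycolysis and lactate genes, 5 were called higher and 4 lower in vitro (adjusted p = 0.0609 and 0.254). Ldha, a lactate dehydrogenase subunit, was 5.11-fold higher, Slc16a1, a carrier of lactate and pyruvate, 2.78-fold and Pdk1, a kinase that inhibits the pyruvate dehydrogenase complex, 2.52-fold higher in the authors' deposited table. Ldha stood at 68.6 ± 13.6 normalised reads in vitro and 13.4 ± 10.1 in vivo (SD, n = 3 libraries each). Gpi1 and Pkm, enzymes of glycolysis, were 1.54-fold and 1.56-fold lower in the authors' deposited table. Named after their values were seen, Gapdh and Aldoa were 1.58-fold and 1.21-fold higher, and Pfkl and Eno1 were 1.47-fold and 1.21-fold lower in the authors' deposited table. The median of the list was -0.12 on the log2 scale. Of 7 members with recovered reads, limma voom called 3 higher over all genes, and 3 higher and 1 lower adjusted over the list alone, and the median log2 change was 0.83 in in vitro library B, 0.03 in library A and -0.23 in library C.

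Of 18 genes of cholesterol synthesis and uptake, 5 were called higher and 1 lower in vitro (adjusted p = 0.0609 and 1). The higher calls passed at a PPEE below 0.01 (adjusted p = 0.0338, range over the alternatives 0.0338 to 0.134). Of the 6 members with recovered reads limma voom called 0, camera gave an adjusted p of 0.792 in the lower direction, and the median log2 changes were 0.11, -0.19 and -0.36 in in vitro libraries A, B and C. Stard4, a sterol carrier, was 2.65-fold higher, Fdps 1.99-fold and Msmo1 1.82-fold higher, and Sqle, an enzyme of the same pathway, was 1.44-fold lower in the authors' deposited table. The other called increases, Nsdhl and Idi1, were higher by 0.59 and 0.58 on the log2 scale in the authors' deposited table and were named after their values were seen. Of 20 genes of lipid droplets and fatty acid oxidation, 1 was called higher and 4 lower (adjusted p = 1 and 0.354), and the median log2 change was -0.37. Acsl1 was 1.73-fold lower, Cd36, a fatty acid carrier, 1.49-fold and Plin3 1.30-fold lower, while Fabp5, a fatty acid binding protein, was 1.87-fold higher in the authors' deposited table. Cpt1a, named after its value was seen, was 3.31-fold lower, from 14.4 to 4.36 mean normalised reads in the authors' deposited table.

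Genes of protein folding were called only lower in vitro, and neither list passed its test at a PPEE below 0.05. Of 11 cytosolic and mitochondrial chaperones, 4 were called lower and 0 higher (adjusted p = 0.0749 and 1). The lower calls passed with at least a 1.5-fold change (adjusted p = 0.0442), and the adjusted p ranged from 0.0442 to 0.310 over the alternatives. Hspa8, an abundant chaperone, was 1.75-fold lower, Hsp90ab1 1.72-fold, Dnajb1 1.63-fold and Hsph1 1.59-fold lower in the authors' deposited table. Of 18 genes of the unfolded protein and integrated stress response, 5 were called lower and 0 higher (adjusted p = 0.0906 and 1). Sel1l was 1.73-fold lower, Ppp1r15a 1.70-fold, Hspa5, the main chaperone of the endoplasmic reticulum, 1.52-fold, Pdia4, named after its value was seen, 1.28-fold and Pdia6 1.21-fold lower in the authors' deposited table. Among the 7 members with recovered reads, which are the less abundant ones, limma voom called 1 higher and 0 lower, over all genes as adjusted over the list alone.

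Most stress and signalling lists held 3 calls or fewer. Of 19 genes of oxidative stress defence, 1 was called higher and 0 lower in vitro (adjusted p = 1 for either). It was Gclc, of glutathione synthesis, at 2.95-fold higher in the authors' deposited table, where Nfe2l2 was 1.53-fold lower with a PPEE of 0.149. Of 12 members with recovered reads, limma voom called 1 higher over all genes and 3 higher adjusted over the list alone. Of 16 genes of iron and selenium handling, 1 was called higher and 2 lower (adjusted p = 1 for either). Sephs2, of selenocysteine synthesis, was 2.81-fold higher, and the iron genes Slc11a2 and Aco1 were 1.51-fold and 1.54-fold lower in the authors' deposited table. Selt, also of this list, was 2.00-fold higher with a PPEE of 0.307 in the authors' deposited table. Of 17 genes of the p53 and DNA damage response, 0 were called higher and 1 lower (adjusted p = 1 for either). It was Brca1 at 2.01-fold lower in the authors' deposited table, where Gadd45a was 2.42-fold higher with a PPEE of 0.0996. In recovered reads the fold of Gadd45a was 1.67 without in vivo library B and 6.62 without in vivo library C. Limma voom called 0 of the 11 recovered members over all genes and 2 higher adjusted over the list alone.

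Of 19 insulin and PI3K signalling genes, 2 were called higher and 3 lower in vitro (adjusted p = 1 and 0.741). These were Akt2, a kinase, at 1.76-fold higher and Pdk1 at 2.52-fold higher in the authors' deposited table. Pdk1 is the pyruvate dehydrogenase kinase counted also under glycolysis, and it is in this list through an alias it shares with Pdpk1, the kinase of this pathway. Pdpk1 was 1.26-fold lower with a PPEE of 0.807 in the authors' deposited table, and without Pdk1 the list held 1 higher call. Kit, Tsc2 and Tsc1, the last named after its value was seen, were 1.84-fold, 1.71-fold and 1.42-fold lower in the authors' deposited table. Limma voom called 2 higher and 1 lower of the 7 recovered members over all genes, and 3 higher and 1 lower adjusted over the list alone, with Pdk1 among those higher. Akt2 was not called over all genes (adjusted p = 0.0508). Of 12 hypoxia response genes, 0 were called higher and 2 lower (adjusted p = 1 and 0.887): Kdm3a was 2.44-fold and P4ha1 1.72-fold lower in the authors' deposited table. Of 6 immediate early genes, 0 were called higher and 1 lower (adjusted p = 1 for either). It was Btg2 at 1.71-fold lower in the authors' deposited table, where Atf3 was 1.70-fold lower with a PPEE of 0.761. Of 6 interferon and innate response genes, 0 were called higher and 1 lower (adjusted p = 1 for either). It was Ddx58 at 1.33-fold lower in the authors' deposited table.

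Markers of other cells of the ovary were called in both directions. Of 13 granulosa cell markers, 4 were called higher and 1 lower in vitro (adjusted p = 0.0749 and 1). The higher calls passed at a PPEE below 0.01 (adjusted p = 0.0353) and with at least a 1.5-fold change (adjusted p = 0.0442), with a range of 0.0353 to 0.213 over the alternatives. Besides Inhba, Inha, the inhibin subunit, was 3.34-fold higher, Gata4, a transcription factor, 4.16-fold and Fshr, the receptor of follicle stimulating hormone, named after its value was seen, 5.08-fold higher in the authors' deposited table. Fshr rose from 2.45 to 12.4 mean normalised reads in the authors' deposited table. Slc18a2, a transporter with 313 mean normalised reads in vivo, fell by 0.59 on the log2 scale in the authors' deposited table. Kitl, Gja1, Nr5a2 and Krt8, named after their values were seen, were 1.08-fold, 1.02-fold, 1.26-fold and 1.71-fold lower in the authors' deposited table. Hsd17b1, Cyp19a1, Greb1 and Serpine2, also named after their values were seen, were 4.55-fold, 1.43-fold, 1.31-fold and 1.03-fold higher in the authors' deposited table, Hsd17b1 with a PPEE of 1, and none of these 8 was called. The recovered markers had median log2 changes against the in vivo mean of 0.74, 0.64 and 0.53 in in vitro libraries A, B and C. Of 11 recovered members, limma voom called 3 higher over all genes, and 5 higher and 1 lower adjusted over the list alone. The list gave an adjusted p of 0.0169 with fry, 0.0664 with camera at the preset correlation, and an adjusted p of 0.808 with an estimated correlation.

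Of 5 blood, immune and endothelial markers, 3 were called lower and 0 higher in vitro (adjusted p = 0.0609 and 1). At a PPEE below 0.01 and with at least a 1.5-fold change the lower calls passed (adjusted p = 0.0353 and 0.0442), and the range over the alternatives was 0.0353 to 0.118. C1qb, a complement subunit made by macrophages, was 2.53-fold lower, Tek, a receptor of endothelial cells, 2.05-fold and Pecam1, an endothelial adhesion molecule, 1.51-fold lower in the authors' deposited table. C1qb stood at 58.1 ± 13.8 normalised reads in vitro and 147 ± 15.2 in vivo (SD, n = 3 libraries each), and Cd68 was 1.32-fold higher with a PPEE of 0.818 in the authors' deposited table. The only measured theca and stroma marker was Hsd3b1, described above. Of 3 cumulus expansion and luteinisation markers, 0 were called. Runx2 was 2.47-fold higher with a PPEE of 0.148 and Cyp11a1 1.67-fold lower with a PPEE of 0.708 in the authors' deposited table.

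Ribosomal protein genes and nuclear genes of oxidative phosphorylation had higher means in vitro across the list, with few called members. Of 74 ribosomal protein genes, 71 had a higher in vitro mean, with a median log2 change of 0.60, and 2 were called higher and 0 lower (adjusted p = 1 for either). Rps2 was 1.90-fold and Rpl4 1.23-fold higher in the authors' deposited table. Of 50 oxidative phosphorylation genes, 43 had a higher in vitro mean, with a median log2 change of 0.44, and 4 were called higher and 0 lower (adjusted p = 1 for either). Uqcrfs1 was 4.97-fold higher, Cox5a 2.62-fold, Atp5c1 1.66-fold and Sdhd 1.38-fold higher in the authors' deposited table. Reads per library were recovered for 41 of the ribosomal protein genes, Rps2 and Rpl4 not among them. These 41 had a median log2 change against the in vivo mean of 1.14 in in vitro library B, 0.18 in library A and 0.07 in library C. For the 25 oxidative phosphorylation genes with recovered reads these medians were 0.98, 0.13 and 0.05. Camera at the preset correlation gave an adjusted p of 0.00136 for ribosomal protein genes and 0.0102 for oxidative phosphorylation. With an estimated correlation it gave an adjusted p of 0.808 for both, and without in vitro library B an adjusted p of 0.392 for both. Of 15 histone genes, 1 was called higher and 0 lower (adjusted p = 1 for either): H1f0, a linker histone, was 2.97-fold higher in the authors' deposited table, where H2afy was 2.02-fold higher with a PPEE of 0.214. Of 15 mitochondrially encoded genes in the fixed list, 0 were in the table.

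Set beside random lists matched on mean and gene length, the medians of some lists lay far out, whether few or many of their members were called. The lowest was the subcortical maternal complex at percentile 0.08, followed by the blood, immune and endothelial markers at 0.0850. Next came the zona pellucida and secreted factors at 0.190 and lipid droplets and fatty acid oxidation at 0.210. The spindle, kinetochore and checkpoint list at 2.05 and meiotic cohesion and recombination at 2.11 followed. The highest were ribosomal proteins at percentile 100, maternal mRNA storage and decay at 99.2, oxidative phosphorylation at 99.2 and granulosa cell markers at 97.6. Matched on mean alone, the zona list lay at percentile 17.5. These percentiles were not adjusted over the 27 lists, and they treat the genes of a list as independent.

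**Figure D3:**
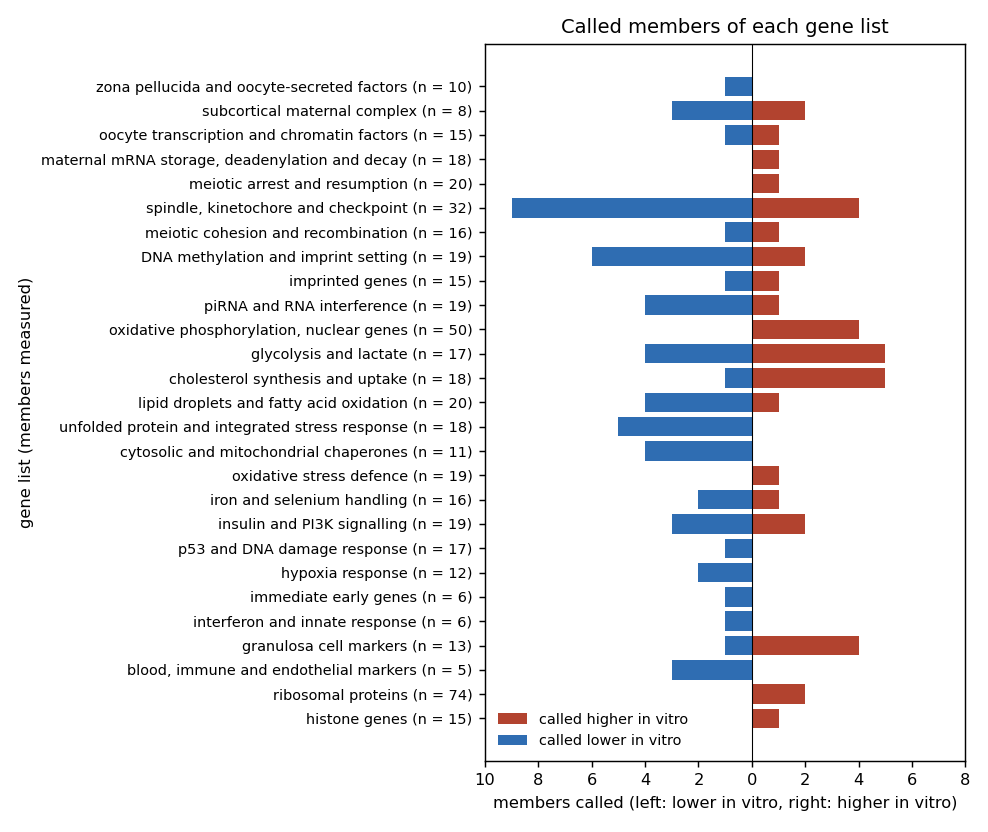
Number of called members of each gene list with at least 5 measured members, with bars to the left for genes called lower in vitro and to the right for genes called higher, by the PPEE of the authors' deposited table. The n in each label is the number of measured members, and the spindle, kinetochore and checkpoint list has the most calls, 9 lower and 4 higher of 32.

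On average, libraries of a group correlated more with each other than with the other group, with in vitro library A as an exception. Across the 5803 recovered genes, the mean Spearman correlation was 0.910 between libraries of a group and 0.835 between groups. The difference of -0.0751 was the lowest of the 10 splits of the 6 libraries (exact permutation test, 1-sided p = 0.1, the smallest these splits allow). In vivo libraries correlated at 0.923 on average and in vitro libraries at 0.898. In vitro library A correlated with in vivo libraries at 0.893 and with its own group at 0.889, while libraries B and C correlated with in vivo libraries at 0.776 and 0.836. These are correlations across genes, which are not independent replicates.

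**Figure D4:**
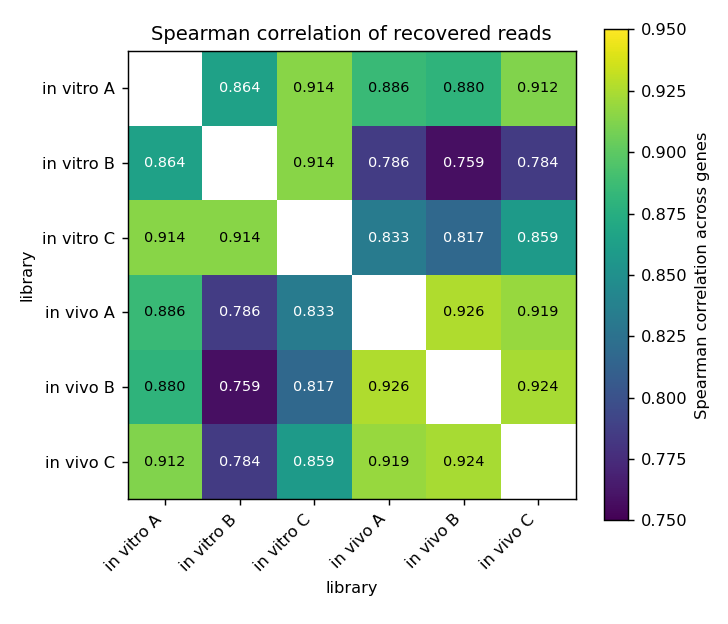
Spearman correlation across 5803 genes of recovered reads for each pair of the 3 in vitro and 3 in vivo libraries, printed in each cell and shown by colour. In vitro library A lies closer to the in vivo libraries than libraries B and C do, with mean correlations of 0.893, 0.776 and 0.836.

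On the recovered reads, limma voom called 388 genes at an adjusted p below 0.05, 218 higher and 170 lower in vitro, of which 311 changed at least 2-fold. The larger direction turned with the scaling, to 190 higher and 219 lower after quantile normalisation, 194 and 231 with totals, and 189 and 233 after centring. The PPEE of the authors' deposited table called 547 of these genes, and 289 were called by both, all in the same direction. Of the 547 calls, 98.9% had groups that did not overlap, against 30.3% of all recovered genes and 10.0% by chance. The PPEE came from the same libraries, so this separation is no independent support for the calls. Leaving out in vitro library A gave 1031 calls, 370 of them among the 388, and leaving out in vivo library A gave 28. Without in vitro libraries B and C there were 121 and 29 calls, and without in vivo libraries B and C 45 and 221.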

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

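The recovered reads, limma voom with or without quality weights, the limit of both means to 100, camera without in vitro library A or B, the 1.5-fold threshold on PPEE calls, the offset of 1, matched genes as background, folds of named genes without 1 library, and the background without genes at a PPEE of exactly 1 were added after seeing the data. Camera, fry and the other limma settings were set before the data were examined, for values per sample, and could run only on the recovered reads. The count of 1640 calls in the authors' deposited table was 1232 at a PPEE below 0.01, 1622 with a mean of at least 10, and 1100 with at least a 1.5-fold change. With the set of called genes held fixed, the share of calls higher in vitro lay between 44.76% and 44.82% under every scaling of the 2 means. After these scalings the median log2 lay within 0.035 of 0, so few directions could turn, and the calls themselves were not redone. The share of genes below 2-fold was 90.3% with a mean of at least 10, where the lowest means drop out (genes with means up to 20 had an SD of log2 changes of 0.92, against 0.63 over all genes), and between 89.0% and 89.9% under the other scalings and offsets.

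Among gene lists, the count past the threshold was 1, and it was 4 at a PPEE below 0.01, 3 with at least a 1.5-fold change, 0 with a mean of at least 10 and 0 without genes at a PPEE of exactly 1, where 9 tests each still had a raw p below 0.05. Against genes matched on mean, and on mean and length, it was 0 and 0, with 8 tests each at a raw p below 0.05. It was 1 without shared members and 1 after centring. At a PPEE below 0.01 the lists past it were DNA methylation (lower), cholesterol (higher), granulosa markers (higher) and blood and endothelial markers (lower), with adjusted p from 0.0338 to 0.0353. With at least a 1.5-fold change they were chaperones (lower), granulosa markers (higher) and blood and endothelial markers (lower), each with an adjusted p of 0.0442. On recovered reads camera gave 2 lists at the preset correlation, 0 with an estimated correlation, 3 without in vitro library A (ribosomal proteins, oxidative phosphorylation and small RNA genes) and 0 without in vitro library B, and fry gave 2. The cause was not tested where the count of lists moved.

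The 388 limma voom calls became 35 at an adjusted p below 0.01, 9 in a test against 1.5-fold, 111 among the 4211 genes with both means at most 100, 774 with quality weights per library, 119 without a variance trend and 1255 with a trend and weights. Fewer calls at stricter thresholds and among fewer genes follow from their construction, and for the weights and the trend the cause was not tested. Other values were 346 with a mean of at least 10, 549 and 468 with a trend at offsets of 1 and 0.1, and 409, 425 and 422 after quantile normalisation, scaling to totals and centring. These 3 scalings turned the share of calls higher in vitro from 56.2% to 46.5%, 45.6% and 44.8%. Leaving out 1 library gave 28 to 1031 calls: 1031, 121 and 29 without in vitro libraries A, B and C, and 28, 45 and 221 without in vivo libraries A, B and C. Of 746 values of named genes under these settings, 523 kept their side of the threshold, 216 fell short of it, 7 passed it anew and 0 changed direction. The recovered fold of 8 named genes, 6 of them among the 16 largest changes, moved more than 2 times without 1 library or lacked in vivo reads, and 0 called genes changed direction.

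The difference in correlation of -0.0751 ranged from -0.122 to -0.0562 over all alternatives that were run, including each left-out library. No paired analysis was possible because the deposited columns are group means and the recovered libraries carry no replicate number. The PPEE, the group means and the counts from them could not be recomputed without single samples, genes absent from the table could not be brought back by dropping a filter, and scaling a library does not alter a rank correlation, so those alternatives, set before the data were examined, were not run. Genes detected per library were not counted. Of 1566 genes with a mean up to 20, 4.73% were called and 35.2% had a PPEE of exactly 1, against 24.2% and 0.895% of 1229 genes above 1000, and the part of depth in this was not tested.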

Other observations

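All tests in this part were chosen after the data were seen, while the marker and ribosomal protein lists they use were fixed before. Of 1972 tests of Gene Ontology terms, 1 passed: hemostasis, with 38 of 214 genes called lower in vitro (adjusted p = 0.0376). The next were integral to membrane, with 50 of 342 genes lower (adjusted p = 0.0832), and nuclear body, with 26 of 175 genes higher (adjusted p = 0.105). Against genes matched on mean, hemostasis and integral to membrane passed (adjusted p = 0.0122 and 0.0111), and against genes matched on mean and length 0 terms did (adjusted p = 0.135 for both). Called members of hemostasis included Itgb3, an integrin of platelets and other cells, at 2.95-fold lower, Serpinc1, the inhibitor of thrombin, at 2.03-fold, F13a1, a clotting factor subunit, at 2.17-fold and Prkcb, a protein kinase, at 3.19-fold lower in vitro in the authors' deposited table. The term also held genes with other known roles, such as the chaperone Hspa5 at 1.52-fold, the egg membrane protein Cd9 at 1.19-fold and the spindle kinesins Kif4 and Kif11 at 1.52-fold and 1.46-fold lower in the authors' deposited table. These genes were chosen after their values were seen.

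A PPEE of exactly 1 was listed for 1627 genes of the authors' deposited table, 149 of which differed at least 2-fold and 16 at least 4-fold. Of the 1366 such genes with recovered reads, 97.7% had a pooled variance within groups below the average of both group means, against 1.80% of the other genes. This variance divides the squares by the number of libraries, not by the degrees of freedom, which makes it smaller. Limma voom called 45 of them, 19 higher and 26 lower in vitro, and these were not among the calls of the authors' deposited table. Klf12, a transcription factor, had 9, 16 and 9 recovered reads in vitro and 0, 1 and 0 in vivo, and Naglu, a lysosomal enzyme, 19, 22 and 11 against 3, 2 and 1. Muc15 had 0, 2 and 1 recovered reads in vitro and 11, 12 and 12 in vivo, and Pdk2, a kinase of the pyruvate dehydrogenase complex, 5, 2 and 0 against 26, 20 and 13.

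In vitro library A lay between the other in vitro libraries and the in vivo ones: genes at least 2-fold higher in the other 2 in vitro libraries had a median log2 change of 0.64 in library A, and the same measure was 1.61 for library B and 1.39 for library C. A mixture with in vivo RNA as the only difference would give 1 share from all genes. Genes higher in vitro gave 0.505 (95% bootstrap interval 0.456 to 0.545) and genes lower in vitro 0.269 (0.222 to 0.313). These intervals resample genes within single libraries and hold no spread between libraries, so the 2 shares cannot decide for or against a mixture. Both shares lay below the value near 1 that an in vivo sample under a wrong label would give. For genes chosen at 4-fold by library C, the intervals overlapped. Library B alone standing apart is argued against by a correlation across genes of 0.361 between C minus A and B minus in vivo (in vivo pairs reached at most 0.166), and a length trend by a correlation of B minus A with C minus in vivo of 0.398 once length was removed. Cultures that differ from each other, or a mixture with or without other differences, may be behind the place of library A. The first was not tested, and the shares cannot decide the second.

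Short genes and ribosomal protein genes had higher in vitro means, with a median log2 change of 0.33 in the shortest 10.0% of genes and 55 genes called higher and 10 lower there. For the 41 of 74 ribosomal protein genes with recovered reads, the values allow library B as the source. Their median log2 change was 1.14 in library B. Libraries A and C, at 0.18 and 0.07, lay inside the range of the in vivo libraries, -0.37 to 0.22. The other ribosomal protein genes, among them the called Rps2 and Rpl4, had no reads per library, so their source was not shown. The shortest of 5 bins of recovered genes had medians of 0.39 in library B, 0.08 in A, 0.02 in C and at most 0.11 in vivo. The rank correlation with length was -0.172 in B and also -0.124 in A. GC content as the whole cause of the length trend is argued against, since the rank correlation of change and length was -0.161 before and -0.152 after removing GC, and the shortest genes outside the highest 10.0% by GC kept a median log2 change of 0.34. For ribosomal protein genes the median lay at percentile 100 of random lists matched on mean and length. Those lists draw genes independently, while the ribosomal protein genes with recovered reads shifted together, mostly in library B. The percentile therefore cannot decide whether length was the whole cause. The highest 10.0% by GC had a shift of their own (median log2 change 0.24, with 111 called higher and 24 lower), and neither its cause nor what sets library B apart, in culture or in library preparation, was tested.

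Inhba, Inha, Gata4 and Fshr were higher in vitro, and granulosa cells left on the oocytes cannot be told apart from expression in the oocytes themselves. Of 10 granulosa markers with an in vivo mean under 100, 6 were higher in vitro and 4 were not (Kitl, Gja1, Nr5a2 and Krt8), and such cells would bring all their abundant transcripts. Inhba, the most changed, stood at 60.1 mean normalised reads in vitro in the authors' deposited table, and the labels name no step that would remove such cells. The low counts of most markers keep this open, and a difference of the oocytes between culture and ovary was not tested apart from it.

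For the 388 limma voom calls, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split, 1 of the 10, gave 388 calls and the highest of the others 0. Each other split mixes libraries of both groups, so any difference between the groups widens its spread and lowers its calls. The 0 calls are therefore no measure of how many calls arise by chance.

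Ccdc82 took 17.0% of the summed in vitro means and 11.1% of the summed in vivo means in the authors' deposited table, and was 1.58-fold higher in vitro there. A stretch of its sequence is shared by 39 genes of the table, in matches of at least 300 bases at 85% identity or more. Shorter matches and those to other stretches were not counted. These 39 genes had a median log2 change of 0.15, with 5 called higher and 4 lower.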
